A study of Homo sapiens with 12 samples.

How the data were processed

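The data are RNA-seq gene counts from 12 libraries of A549 cells, 3 for each combination of line (doxycycline-inducible wild-type PRC1 or PRC1-NLS3A) and treatment (250 ng/ml doxycycline for 2 days, or none). Per the labels' protocols, poly(A) RNA was selected from total RNA before cDNA libraries were made and sequenced. The authors deposited a matrix of raw read counts per gene and library. Per the submitters' processing notes, reads were aligned with HISAT2 to hg19 and counted with featureCounts; versions, the strand setting and the treatment of reads that fit several genes are not given in the sources used here. Overlapping or antisense genes and near-identical paralogs, such as tubulin, histone, HLA and ribosomal protein genes and MTRNR2L8, are therefore uncertain as single genes.

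The authors also deposited 2 tables of their own limma comparisons, with log2 fold changes, average log2 expression, p-values and adjusted p-values, and the test scores of limma, per the file headers. Both hold 14880 genes, which is the number of genes with at least 0.5 CPM in at least 2 libraries of the matrix, and their average expression is identical. Each has 1 entry without a gene ID. These tables were used for gene names and for counts of calls beside those computed here, and each such value is named as the authors' deposited table.

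The matrix holds 25702 genes by Entrez Gene ID. Symbols came from the authors' tables for 14358 genes and from a RefSeq table of a GRCh38 assembly for 9370; 1974 IDs had no name and are given by ID. Because the reference in use here is of another build than hg19, no coordinates are given. Every matrix column was mapped to its sample by its name, and groups and replicate numbers come from the sample titles.

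Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 13658 genes with 99.9% of all counts, and libraries were scaled by TMM. A quasi-likelihood model with robust dispersion estimates and 1 mean per group was fitted to all 12 libraries (8 residual degrees of freedom), so all groups share 1 estimate of the spread. Contrasts were induced against non-induced in each line, the difference between these (NLS3A minus WT), and NLS3A against WT without induction. Tests are two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The SE of a log2 fold change is its absolute value divided by the square root of F, and 95% intervals use the moderated degrees of freedom. CPM per library are TMM-scaled.

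Designs, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. There were 22 gene lists from textbook knowledge; of 865 entries, 1 was not found in the matrix. Lists were tested with camera in limma 3.58.1 (preset correlation of 0.01, adjusted over the lists within a comparison), beside camera with a correlation estimated from these libraries, and fry. With an estimated correlation the p53, G2/M, G1/S and interferon lists held in both lines, and in the difference between the lines only the p53 list held. Those calls held by fry too. By fry ATF4 targets (adjusted p = 0.00026 in WT and 0.0023 in NLS3A) and lysosome genes (0.0078 and 0.010) were called as well. In WT alone fry also called the cholesterol (0.0021), chaperone (0.010), matrix (0.045) and leukocyte and endothelium (0.045) lists, and in NLS3A alone NF-kB genes (0.010). Some lists share members, for example GDF15 and LIF in the p53 and secretion lists, SESN2 in the p53 and ATF4 lists and TRIM22 in the p53 and interferon lists. Named in every case were PRC1, CDKN1A, MDM2, GDF15, LMNB1, MKI67, CCNB1, IL6, CXCL8 and GLB1. Of the genes named in every case and by the rule, 2 are not reported. For each line the rule added the members of each list past the threshold with the largest absolute log2 change and a mean log2 CPM of at least 1 (up to 4 for the p53 and cell-cycle lists, 3 for the secretion and tubulin lists, 2 for others). It also added the 8 highest and 8 lowest genes outside the lists in which every induced library lay beyond every non-induced library. For the non-induced lines it took the 8 highest and 8 lowest genes past the threshold. Chosen after their values were seen were FAS, BBC3 and ASNS in both lines, CXCL5, TRIML2, TPPP, TPPP3 and TP53I13 in the WT line, TUBA1C in the NLS3A line and FGB and BCL3 in the non-induced lines. The same holds for CD38, MUC3A, TPPP, TPPP3, MTRNR2L8 and DDIT3 in the difference between the lines.

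Alternatives were DESeq2 size factors, library totals alone, PRC1 left out of scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, each line fitted alone, a replicate block within each line or over both, each library left out in turn and a minimum absolute log2 change of 1. Chosen after seeing the data were a covariate for the mean log2 CPM of ribosomal protein genes, centred within each group or not, leaving out WT_noDox replicate 2 and WT_withDox replicate 3 together, and leaving out mitochondrial genes.

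Replicates of a group were compared by a chi-square of their counts. The statistic per gene ranged from 5.89 to 30.2 over the WT pairs and from 1.99 to 5.06 over the NLS3A pairs. No pair agreed within sampling noise, and each library counts as 1 replicate. Depth ranged from 8998696 to 18055650 counts; 3 counts, taken as the floor, correspond to 0.17 to 0.33 CPM, and this floor covers counting error only.

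The fit was tested on simulated counts drawn for 13658 genes from the real means, dispersions and library sizes. In each, 200 genes were changed and the 53 p53-list members raised 1.25-fold, and false calls were counted among the 13405 other genes. Genes were drawn independently, without the drift that list members share in the real libraries. The shares and false calls below therefore do not cover such drift. All groups were given the same dispersion per gene, while real WT replicates had a larger chi-square per gene than NLS3A replicates. The shares thus do not describe each line's own spread. Each share is of 50 genes without repeated draws, so differences between the comparisons can be sampling noise. In the simulated WT comparison 26.0%, 68.0%, 86.0% and 96.0% of genes changed by 1.25, 1.5, 2 and 3 fold were recovered, with 11 false calls. In the simulated NLS3A comparison the shares were 10.0%, 66.0%, 80.0% and 96.0%, with 10 false calls. For the difference between the lines they were 2.00%, 36.0%, 72.0% and 88.0%, with 12 false calls, and for the non-induced lines 12.0%, 76.0%, 86.0% and 96.0%, with 15. How often other groupings of the same libraries gave as many genes was counted over all 10 splits of 6 libraries, or 100 regroupings for the difference between the lines.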

Results

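Poly(A) RNA was sequenced from A549 cells, an established human lung epithelial carcinoma line. Derivatives of this line held a doxycycline-inducible, flag-tagged PRC1 construct, either the wild-type sequence (WT line) or PRC1 with mutated nuclear localization signals (NLS3A line). PRC1 bundles antiparallel microtubules at the spindle midzone and is needed for cytokinesis. Each line was left non-induced or received 250 ng/ml doxycycline for 2 days, which gave 4 groups of 3 libraries. The mutant was made to separate nuclear from other functions of PRC1, so the questions are which genes changed on induction in each line and whether the 2 responses differed. The libraries held 8998696 to 18055650 counts in genes, and 13658 genes were tested. Values below are TMM-scaled CPM as mean ± SD of 3 libraries, log2 fold changes ± SE, and adjusted p from edgeR. The labels do not say whether the 3 libraries of a group came from separate cultures. The p-values thus measure only the spread between these libraries, pooled over the 4 groups.

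Induction raised PRC1 (Entrez Gene 9055) in both lines. In the WT line PRC1 went from 250.1 ± 14.02 to 1030.5 ± 68.7 CPM, a 4.12-fold rise (95% interval 3.65 to 4.64, adjusted p = 6.9e-11). In the NLS3A line it went from 245.9 ± 13.0 to 933.8 ± 62.1 CPM, a 3.80-fold rise (95% interval 3.37 to 4.28, adjusted p = 1.8e-10). The difference between the log2 changes, NLS3A minus WT, was -0.12 ± 0.11 with a 95% interval of -0.35 to 0.12. Counts per gene do not separate construct-derived from endogenous PRC1 transcripts.

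**Figure D1:**
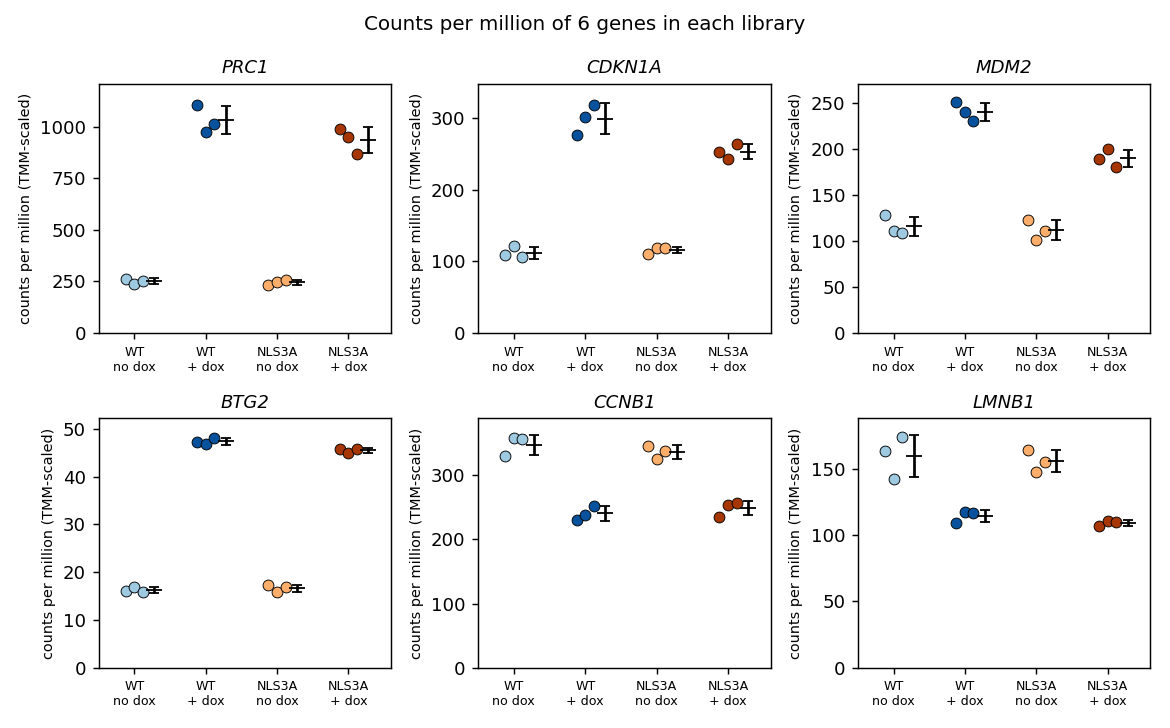
CPM (TMM-scaled, linear axes from 0) of PRC1, CDKN1A, MDM2, BTG2, CCNB1 and LMNB1 in each of the 12 libraries. Points are libraries, and bars are the mean ± SD of 3 libraries per group. In every panel all 3 induced libraries of a line lie on the same side of its 3 non-induced libraries, as for PRC1 at 1030.5 ± 68.7 against 250.1 ± 14.02 in the WT line.

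In the WT line, genes that p53 activates rose together and cell-cycle genes fell together. CDKN1A (Entrez Gene 1026), the p21 inhibitor of cyclin-dependent kinases, rose 2.67-fold from 111.8 ± 8.14 to 298.8 ± 21.6 CPM (log2 change 1.42 ± 0.08, adjusted p = 2.4e-09). MDM2 (4193), the ubiquitin ligase that limits p53, rose 2.07-fold from 116.0 ± 10.8 to 240.7 ± 10.2 CPM (adjusted p = 3.7e-07). CCNB1 (891), the cyclin of mitotic entry, fell by 0.53 ± 0.07 on the log2 scale, from 347.1 ± 15.8 to 240.3 ± 11.1 CPM (adjusted p = 8.1e-05). Lamin B1, LMNB1 (4001), whose loss is a common mark of senescent cells, fell by 0.48 ± 0.08, from 159.7 ± 15.7 to 114.2 ± 4.75 CPM (adjusted p = 0.00045).

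Of 53 measured members of the p53-activated list, 42 were higher in the WT line, 0 were lower and 11 did not pass; adjusted over the list alone, 46 were higher and 1, TP53I13, was lower (-0.29, adjusted p = 0.10 over all genes). Their median log2 change was 0.56, a 1.47-fold rise, and the list test held (adjusted p = 7.7e-07 with an estimated correlation). ABCA12, a lipid transporter, rose by 1.78 ± 0.23, TP53INP1 (94241), a stress-induced p53 cofactor, by 1.75 ± 0.14, BTG2 (7832), an antiproliferative factor, by 1.54 ± 0.08, and SPATA18, a mediator of mitochondrial quality control, by 1.44 ± 0.13. The death receptor FAS rose by 1.05 ± 0.09, the apoptosis inducer BBC3 by 0.80 ± 0.11 and the secreted factor GDF15 (9518) by 0.69 ± 0.10.

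Of 74 measured G2/M and mitosis genes, 0 were higher, 68 were lower and 6 did not pass; adjusted over the list alone, all 74 were lower. The median was -0.49 (adjusted p = 6.6e-05 with an estimated correlation). PTTG1 (9232), the securin that holds back separase, fell by 0.84 ± 0.14, BIRC5 (332), the survivin subunit of the chromosomal passenger complex, by 0.82 ± 0.11, its kinase AURKB (9212) by 0.69 ± 0.10 and the helicase PIF1 by 0.69 ± 0.11. The proliferation marker MKI67 (4288) did not pass, at -0.30 ± 0.12 (adjusted p = 0.10), though it did without WT_noDox replicate 2 (0.010) and in 6 alternatives in all. Of 64 G1/S and DNA replication genes, 0 were higher, 59 were lower and 5 did not pass, with 63 lower when adjusted over the list alone and a median of -0.46 (adjusted p = 0.00043 with an estimated correlation). The replication fork factor CDC45 (8318) fell by 0.73 ± 0.09, the transcription factors E2F2 and E2F1 (1869) by 0.73 ± 0.13 and 0.72 ± 0.10, and the checkpoint mediator CLSPN by 0.70 ± 0.12.

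Genes for secreted factors of senescent cells did not move as a group in the WT line. Of 32 measured members, 4 were higher, 3 were lower and 25 did not pass, with 4 higher and 4 lower when adjusted over the list alone and a median of -0.09 (camera adjusted p = 0.43, 0.74 with an estimated correlation). GDF15 and STC1 (log2 change 0.67 ± 0.14) were among those that rose, while the cytokine IL11 fell by 0.59 ± 0.09 and the chemokine CXCL5 by 0.47 ± 0.06. The chemokine CXCL8 (3576) was at 2.40 ± 0.31 against 2.15 ± 0.10 CPM and did not pass (0.14 ± 0.24, adjusted p = 0.74). IL6 (3569) had 10 counts summed over the 12 libraries, at most 2 in any library, and was not tested. GLB1 (2720), which encodes lysosomal beta-galactosidase, did not pass at 0.05 ± 0.08 (95% interval -0.12 to 0.22, adjusted p = 0.76).

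Tubulin genes moved in different directions. Of 14 measured members 2 were higher, 1 was lower and 11 did not pass, also when adjusted over the list alone (camera adjusted p = 0.87, 0.92 with an estimated correlation). TUBA1A (7846) rose by 0.79 ± 0.11, from 20.5 ± 0.465 to 35.5 ± 4.31 CPM, and TUBB4A (10382) by 0.58 ± 0.10. The more abundant TUBA1C (84790) fell by 0.45 ± 0.10, from 708.9 ± 127 to 520.2 ± 31.4 CPM. Tubulin genes are close paralogs, and how reads that fit several of them were counted is not given in the sources used here. Of 47 microtubule-associated and stability genes, 6 were higher, 3 lower and 38 not past, with the same counts adjusted over the list alone (camera adjusted p = 0.36, 0.74 with an estimated correlation). The end-binding protein MAPRE3 (22924) rose by 0.78 ± 0.09.

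Interferon-stimulated genes rose in the WT line. Of 35 measured members, 13 were higher, 0 were lower and 22 did not pass, with 20 higher when adjusted over the list alone and a median of 0.31 (adjusted p = 0.015 with an estimated correlation). SAMD9L rose by 1.24 ± 0.31 and IFIT2 by 0.99 ± 0.28, both at under 4 CPM. SAMD9L was no longer past the test without WT_noDox replicate 3 (adjusted p = 0.055) or WT_withDox replicate 1 (0.071), and IFIT2 without WT_noDox replicate 2 (0.051) or 3 (0.10) or WT_withDox replicate 1 (0.086) or 3 (0.084). The count fell to 8 members without WT_noDox replicate 3 and to 7 without WT_withDox replicate 1.

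Of 44 target genes of the stress factor ATF4, 1 was higher, 14 were lower and 29 did not pass in the WT line, with 22 lower and 1 higher adjusted over the list alone. The median was -0.21 (camera adjusted p = 3.3e-07, adjusted p = 0.082 with an estimated correlation). The member that rose was SESN2 (83667), also a p53 target, by 0.86 ± 0.09. The serine synthesis enzyme PHGDH (26227) fell by 0.53 ± 0.08 and asparagine synthetase, ASNS (440), by 0.47 ± 0.08. The count of lower members was 7 without WT_noDox replicate 3 or WT_withDox replicate 1, and 9 with library totals alone.

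Other lists were called by camera in the WT line with the preset correlation but not with an estimated one. Of 49 lysosome genes 8 were higher, 1 lower and 40 not past (12 and 2 adjusted over the list alone), with a median of 0.11 (adjusted p = 0.35 with an estimated correlation) and no call without WT_noDox replicate 1 (0.063). Of 41 epithelial-mesenchymal and matrix genes 3 were higher, 1 lower and 37 not past, also adjusted over the list alone, with a median of 0.12 (adjusted p = 0.39 with an estimated correlation) and no call without WT_withDox replicate 1 (0.052). Of 13 replication-dependent histone genes 5 were higher, 0 lower and 8 not past, also adjusted over the list alone (median 0.19, adjusted p = 0.49 with an estimated correlation). That call was lost without WT_noDox replicate 1 (0.31) or WT_withDox replicate 3 (0.084, where the median was -0.08). Of 53 nuclear OXPHOS genes 0 were higher, 2 lower and 51 not past (0 and 1 adjusted over the list alone), with a median of -0.20 (adjusted p = 0.74 with an estimated correlation) and no call without WT_noDox replicate 2 (0.22). None of 75 ribosomal protein genes passed, also adjusted over the list alone (median -0.20, adjusted p = 0.74 with an estimated correlation), and without WT_noDox replicate 2 the call was lost (0.97).

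Within the lists the smooth muscle actin ACTA2 (59) rose by 1.78 ± 0.11, from 8.87 ± 1.06 to 30.2 ± 0.23 CPM, and keratin KRT19 by 0.71 ± 0.12. The sterol reductase TM7SF2 (7108) rose by 1.06 ± 0.13 and the sterol isomerase EBP (10682) fell by 0.72 ± 0.11. The other lists were not called (camera adjusted p from 0.056 to 0.87). The following counts are of members higher and lower, then of those adjusted over the list alone, and the remaining members did not pass. NF-kB early genes had 0 and 2 of 27 (0 and 2), YAP/TEAD targets 3 and 5 of 29 (3 and 7), NRF2 targets 5 and 2 of 39 (5 and 2) and cholesterol synthesis genes 1 and 7 of 30 (2 and 9). Chaperone and unfolded protein genes had 1 and 3 of 31 (1 and 7), and were called without WT_noDox replicate 2 (0.044) or WT_withDox replicate 2 (0.044). They were also called with no filter (0.0099), with DESeq2 (0.017), with limma-voom (0.026) and without mitochondrial genes (0.039). Cholesterol synthesis genes were called with no filter (0.039), and NRF2 targets with the ribosomal protein covariate not centred (0.042). Markers of fibroblasts had 0 and 1 of 4, of leukocytes and endothelium 0 and 1 of 5 and of alveolar type II and airway epithelium 0 and 0 of 5, each also adjusted over the list alone. Of the 13 mitochondrially encoded mRNAs 0 passed, also adjusted over the list alone, and they were called with a median of -0.42 without WT_withDox replicate 1 (0.0070) and of 0.35 without WT_withDox replicate 3 (0.013). The median was positive where the list test pointed down for mitochondrially encoded mRNAs (0.01) and fibroblast markers (0.14).

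Genes outside the lists were taken from those past the test with every induced library beyond every non-induced library, which chance gives for 10% of genes. The 8 highest in the WT line were WDR63 (2.30 ± 0.19), ZNF608 (2.28 ± 0.26), GRHL3 (2.24 ± 0.22), INPP5D (2.15 ± 0.36), SLC52A1 (2.10 ± 0.18), CYGB (2.06 ± 0.34), GRIN2C (2.05 ± 0.25) and PLXNB3 (1.89 ± 0.23). GRHL3 is an epithelial transcription factor, SLC52A1 a riboflavin transporter and PLXNB3 a semaphorin receptor. Most had low levels, with SLC52A1 going from 1.84 ± 0.22 to 7.87 ± 0.73 CPM. The growth factor-binding protein IGFBP1 (3484) fell by 1.12 ± 0.19, the imprinted RNA H19 (283120) by 1.02 ± 0.17 and FBXO43, an inhibitor of the anaphase-promoting complex, by 0.82 ± 0.14.

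Over all genes, 818 were higher and 867 lower in the induced WT libraries, and 3846 had an unadjusted p under 0.05 where 682.9 would by chance. With an absolute log2 change of at least 1, 121 were higher and 9 lower. The authors' deposited table for this contrast listed 785 higher and 829 lower genes, and 1596 genes were called in both. The counts rose to 1843 and 2189 without WT_noDox replicate 1 and fell to 422 and 466 without WT_noDox replicate 3 and to 453 and 427 without WT_withDox replicate 1. Scaling by library totals alone gave 1074 higher and 601 lower genes, 64.1% higher against 48.5%. With the WT line fitted alone, 329 genes were higher and 280 lower.

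**Figure D2:**
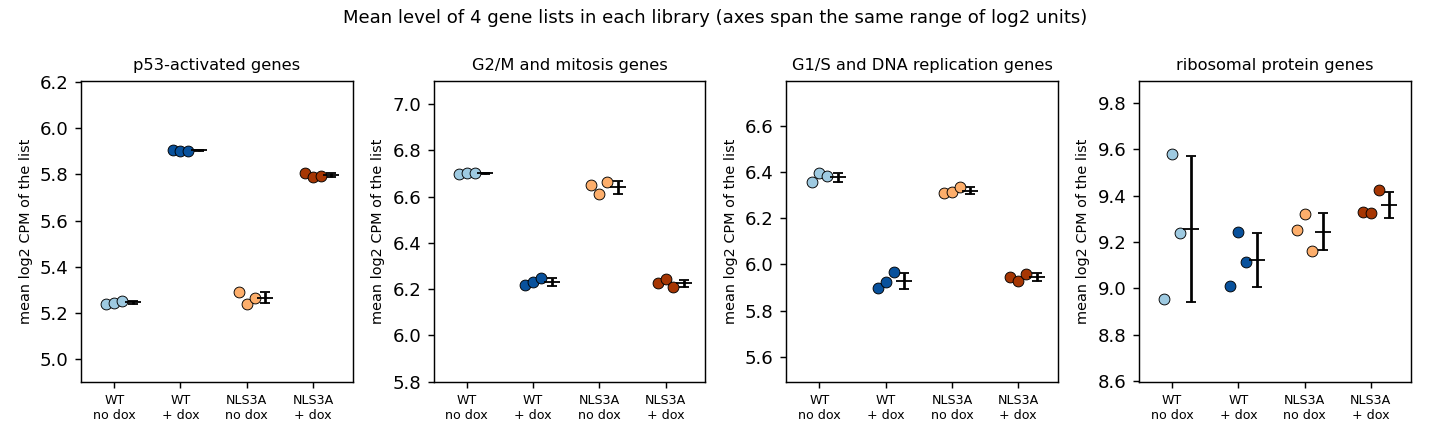
Mean log2 CPM of the p53-activated, G2/M, G1/S and ribosomal protein lists in each library, on axes that span the same range of log2 units. Points are libraries, and bars are the mean ± SD of 3 libraries per group. The p53 list lies at 5.90 to 5.91 in induced WT and 5.79 to 5.81 in induced NLS3A libraries, and the ribosomal protein list spans 8.95 to 9.58 within the non-induced WT libraries.

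In the NLS3A line p53-activated genes rose and both cell-cycle lists fell, as in the WT line. CDKN1A rose 2.18-fold, from 115.8 ± 4.25 to 252.8 ± 10.6 CPM (log2 change 1.13 ± 0.08, adjusted p = 7.9e-08). MDM2 rose by 0.76 ± 0.08, from 112.2 ± 10.9 to 190.1 ± 9.69 CPM (adjusted p = 4.2e-05), BTG2 by 1.45 ± 0.08 and GDF15 by 0.75 ± 0.10. CCNB1 fell by 0.43 ± 0.07, from 335.5 ± 10.7 to 248.6 ± 11.5 CPM (adjusted p = 0.00094), and LMNB1 by 0.51 ± 0.08, from 155.4 ± 8.21 to 108.9 ± 2.22 CPM (adjusted p = 0.00065). CXCL8 (0.26 ± 0.26, adjusted p = 0.67) and GLB1 (0.09 ± 0.08, adjusted p = 0.65) did not pass. MKI67 did not pass either (-0.41 ± 0.12, adjusted p = 0.055), though it did without WT_noDox replicate 1 (0.0014) or 2 (0.0082) or WT_withDox replicate 1 (0.044), by DESeq2 (0.018) and by limma-voom (0.048), and in 11 alternatives in all.

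Of the 53 p53-activated genes, 36 were higher in the NLS3A line, 0 lower and 17 not past, with 44 higher when adjusted over the list alone. The median was 0.47, a 1.39-fold rise (adjusted p = 4.0e-07 with an estimated correlation). TP53INP1 rose by 1.25 ± 0.14, SPATA18 by 1.08 ± 0.14, BBC3 by 1.04 ± 0.11 and FAS by 0.87 ± 0.09. Of the 74 G2/M and mitosis genes, 62 were lower, 0 higher and 12 not past, with 74 lower when adjusted over the list alone and a median of -0.42 (adjusted p = 2.3e-05 with an estimated correlation). SPC25, a kinetochore subunit, fell by 0.70 ± 0.09, cyclin A2, CCNA2, by 0.54 ± 0.07, the kinase MELK by 0.53 ± 0.07 and the spindle motor KIF11 by 0.52 ± 0.09. Of the 64 G1/S and DNA replication genes, 51 were lower, 0 higher and 13 not past, with 61 lower when adjusted over the list alone and a median of -0.38 (adjusted p = 0.00032 with an estimated correlation). The epigenetic regulator UHRF1 fell by 0.61 ± 0.09 and the nuclease EXO1 by 0.54 ± 0.08. The G1/S count was 28 without NLS3A_noDox replicate 1, 33 without NLS3A_noDox replicate 3 and 27 without NLS3A_withDox replicate 1 or 2.

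TUBA1A and TUBB4A rose in the NLS3A line as well, by 0.78 ± 0.11 and 0.58 ± 0.10, and the other 12 measured tubulin genes did not pass, also when adjusted over the list alone (camera adjusted p = 0.14, 0.69 with an estimated correlation). TUBA1C was at 573.7 ± 25.3 against 673.9 ± 7.58 CPM (-0.23 ± 0.10, adjusted p = 0.22), and passed without WT_noDox replicate 1 (0.045). MAPRE3 rose by 0.51 ± 0.09 within a list in which 2 of 47 members were higher, 1 was lower and 44 did not pass, with 2 and 2 adjusted over the list alone (camera adjusted p = 0.74). Outside the lists, TPPP3 (51673) and TPPP (11076), which promote tubulin polymerization, fell by 1.95 ± 0.21 and 0.89 ± 0.13, TPPP3 from 13.5 ± 2.65 to 3.54 ± 0.67 CPM. In the WT line TPPP3 fell by 0.77 ± 0.20 (adjusted p = 0.017), a call lost without WT_noDox replicate 3 (0.067) or WT_withDox replicate 1 (0.13), and TPPP did not pass (-0.27 ± 0.13, adjusted p = 0.18). The differences between the lines did not pass for either gene (adjusted p = 0.92). For TPPP3 the difference did pass without WT_noDox replicate 1 (0.049) and with a ribosomal protein covariate, centred within groups (0.0013) or not (0.0018).

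Of the secreted factors of senescent cells, 2 of 32 were higher, 4 lower and 26 not past in the NLS3A line, also adjusted over the list alone (camera adjusted p = 0.32, 0.73 with an estimated correlation). EREG, an EGF receptor ligand, fell by 0.60 ± 0.10 and CXCL5 by 0.55 ± 0.06. Interferon-stimulated genes had 5 of 35 members higher, 0 lower and 30 not past, with 10 higher and 1 lower when adjusted over the list alone and a median of 0.26 (adjusted p = 0.033 with an estimated correlation). The count of higher members was 9 without WT_noDox replicate 1 or 2 and 3 without WT_withDox replicate 1 or 2. It was 3, 2 and 2 without NLS3A_noDox replicates 1, 2 and 3, and 2, 1 and 1 without NLS3A_withDox replicates 1, 2 and 3.

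ATF4 targets had 2 higher, 4 lower and 38 not past of 44 in the NLS3A line, with 3 higher and 20 lower adjusted over the list alone and a median of -0.17 (adjusted p = 0.12 with an estimated correlation). SESN2 rose by 0.70 ± 0.09. ASNS fell by 0.35 ± 0.08, a call lost without NLS3A_noDox replicate 3 (adjusted p = 0.073) or NLS3A_withDox replicate 1 (0.083) or 2 (0.055). The count of lower members was 14 without WT_noDox replicate 1, 13 without WT_noDox replicate 2, 7 without WT_withDox replicate 3 and 1 without NLS3A_noDox replicate 3 or NLS3A_withDox replicate 1 or 2. Some lists were called only with the preset correlation. Lysosome genes had 4 of 49 higher, 0 lower and 45 not past (9 and 2 adjusted over the list alone), with a median of 0.10 (adjusted p = 0.22 with an estimated correlation). Of 75 ribosomal protein genes 0 passed, also adjusted over the list alone (median 0.10, adjusted p = 0.89 with an estimated correlation), and the call was lost without NLS3A_noDox replicate 3 (0.22) or NLS3A_withDox replicate 3 (0.30). Of 13 mitochondrially encoded mRNAs 0 passed, also adjusted over the list alone (median 0.68, adjusted p = 0.47 with an estimated correlation).

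The remaining lists were not called in the NLS3A line (camera adjusted p from 0.055 to 0.85), and counts are given as in the WT line. NF-kB early genes had 0 higher and 3 lower of 27 (0 and 3), among them PTGS2, the inducible cyclooxygenase, at -0.72 ± 0.13. YAP/TEAD targets had 0 and 3 of 29 (0 and 5), among them the growth factor-binding protein IGFBP3 at -0.45 ± 0.07. As a list they were called without NLS3A_noDox replicate 1 (0.030) or 2 (0.015) or NLS3A_withDox replicate 1 (0.022) or 2 (0.038), and with no filter (0.018). NRF2 targets had 0 and 1 of 39 (0 and 0), cholesterol synthesis genes 1 and 2 of 30 (3 and 4), chaperone genes 0 and 0 of 31 (0 and 0), matrix genes 3 and 0 of 41 (3 and 0) and OXPHOS genes 0 and 0 of 53 (0 and 0). Histone genes had 0 and 0 of 13 (1 and 0) and were called without NLS3A_withDox replicate 1 (0.020). They were also called with library totals alone (0.047), no filter (0.018) and a replicate block within each line (0.045). Markers of fibroblasts had 0 and 0 of 4 (0 and 0), of leukocytes and endothelium 0 and 0 of 5 (0 and 1), and of lung epithelium 0 and 1 of 5 (0 and 1), the mucin MUC5B at -1.16 ± 0.24. The list test pointed up with a median of -0.0033 for matrix genes, and down with a median of 0.12 for lung epithelium markers. For microtubule-associated genes it pointed down with a median of -0.015 and a mean of 0.019.

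ACTA2 rose by 1.41 ± 0.11 and TM7SF2 by 0.91 ± 0.13 in the NLS3A line. Outside the lists SLC52A1 rose by 2.14 ± 0.19, GRIN2C by 2.13 ± 0.28, WDR63 by 1.93 ± 0.22, GRHL3 by 1.74 ± 0.22, ZNF608 by 1.72 ± 0.26, PLXNB3 by 1.67 ± 0.25 and TRIML2 by 1.66 ± 0.11. H19 fell by 1.26 ± 0.16, IGFBP1 by 1.01 ± 0.19 and the NAD hydrolase CD38 (952) by 0.98 ± 0.15.

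Over all genes, 337 were higher and 389 lower in the induced NLS3A libraries, and 2448 had an unadjusted p under 0.05. With an absolute log2 change of at least 1, 59 were higher and 7 lower. The authors' deposited table listed 303 higher and 368 lower genes, and 662 genes were called in both. Without NLS3A_noDox replicates 1, 2 and 3 in turn, 178, 252 and 204 genes were lower, and 170 and 178 were higher without replicates 1 and 3. Without NLS3A_withDox replicates 1, 2 and 3 in turn, 174, 177 and 195 were higher and 172, 177 and 200 lower. Without WT_noDox replicate 1 the counts were 560 and 648, and 592 were lower without WT_noDox replicate 2. With each line fitted alone the NLS3A counts were 857 and 929 and the WT counts 329 and 280, so which line had more genes called turned, from 1685 in WT and 726 in NLS3A to 609 and 1786. The main fit shares 1 estimate of the spread, while the chi-square per gene between replicates was 5.89 to 30.2 in WT and 1.99 to 5.06 in NLS3A. The main counts thus do not rest on each line's own spread.

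The responses of the 2 lines overlapped. Of the genes called, 262 were higher in both lines where independent lists would share 20.2, 304 were lower in both where 24.7 would be shared, and 0 were called in opposite directions. These comparisons have no library in common, but they share 1 estimate of each gene's spread, which can add to the overlap. Of the 818 genes higher in the WT line, 798 had a positive log2 change in the NLS3A line, and of the 867 lower genes, 841 had a negative one. The log2 changes had a Pearson r of 0.58 across genes, which are not independent replicates.

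**Figure D3:**
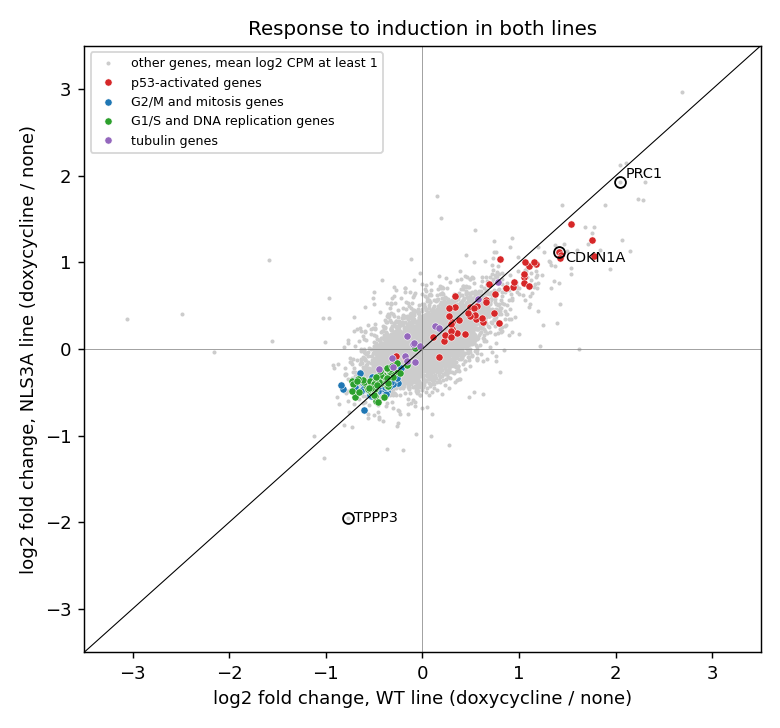
Log2 fold change on induction in the NLS3A line (vertical axis) against the WT line (horizontal axis) for genes with a mean log2 CPM of at least 1 (grey) and for 4 gene lists (coloured points); the diagonal marks equal changes. The p53-activated genes lie to the upper right (medians 0.56 and 0.47) and both cell-cycle lists to the lower left (G2/M medians -0.49 and -0.42).

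No gene passed the test of a different response in the 2 lines: 0 had a larger and 0 a smaller log2 change in NLS3A by edgeR, DESeq2 or limma-voom. By edgeR 544 had an unadjusted p under 0.05, fewer than the 682.9 that chance would give. The absence of calls does not show that the responses were alike. The difference, NLS3A minus WT, was -0.29 ± 0.11 for CDKN1A, -0.29 ± 0.12 for MDM2, 0.10 ± 0.10 for CCNB1 and -0.03 ± 0.11 for LMNB1 (adjusted p from 0.92 to 0.97). Larger and smaller refer to the sign of NLS3A minus WT, so a gene that fell further in NLS3A counts as smaller. Without WT_noDox replicate 1, 186 genes had a larger and 48 a smaller change in NLS3A. With a ribosomal protein covariate centred within groups the counts were 179 and 68, and with that covariate not centred they were 0 and 4. As a list, the 53 p53-activated genes rose less in the NLS3A line, with a median difference of -0.11, a positive difference for 10 members and a change of smaller absolute size for 46 (camera adjusted p = 8.7e-06, adjusted p = 0.0078 with an estimated correlation). That call was lost without WT_noDox replicate 1 (adjusted p = 0.15 with an estimated correlation), where the median difference was -0.15. It was also lost with library totals alone (0.088) and with a replicate block within each line (0.115), and over its alternatives that value ranged from 0.0043 to 0.155.

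Both cell-cycle lists fell less in NLS3A by camera with the preset correlation, but not with an estimated one (adjusted p = 0.37 for both). The median difference was 0.071 for G1/S and 0.032 for G2/M genes, though for G2/M genes it was -0.022 and not called (0.14) with library totals alone. The G2/M call was also lost without WT_noDox replicate 1 (0.095), WT_withDox replicate 1 (0.071) or 2 (0.070), NLS3A_noDox replicate 2 (0.24) or NLS3A_withDox replicate 2 (0.068). Tubulin genes had a median difference of 0.10 (adjusted p = 0.42 with an estimated correlation), with the preset call lost with library totals alone (0.066). It was also lost without WT_noDox replicate 2 (0.25), WT_withDox replicate 1 (0.15) or 2 (0.15), NLS3A_noDox replicate 1 (0.18) or 2 (0.073) or NLS3A_withDox replicate 1 (0.074) or 3 (0.05001).

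The preset correlation also called ribosomal protein genes (median difference 0.28, adjusted p = 0.37 with an estimated correlation), nuclear OXPHOS genes (0.21, 0.41) and mitochondrially encoded mRNAs (0.67, 0.37). Mitochondrially encoded mRNAs took 3.51% ± 0.17 of counts in induced and 2.28% ± 0.46 in non-induced NLS3A libraries, against 2.22% ± 1.08 and 2.16% ± 0.44 in the WT line. The mean log2 CPM of ribosomal protein genes differed by more within the non-induced WT libraries, from 8.95 to 9.58, than between any pair of group means. Chaperone genes (0.065, 0.37) lost the preset call without WT_noDox replicate 3 (0.072) or NLS3A_withDox replicate 3 (0.05001), and YAP/TEAD targets (-0.10, 0.41) without WT_noDox replicate 2 (0.070) or NLS3A_noDox replicate 3 (0.057). Matrix genes (-0.12, 0.37) lost it without WT_withDox replicate 1 (0.066) or 2 (0.056) or NLS3A_noDox replicate 3 (0.082).

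The other 12 lists did not differ between the lines by camera, and in all 22 lists 0 members passed, also adjusted over the list alone. With DESeq2 microtubule-associated genes (0.033) and ATF4 targets (0.025) were called. With 1 library left out some of these lists were called. Microtubule-associated genes were called without WT_noDox replicate 1 (adjusted p = 0.024), WT_withDox replicate 2 (0.034), NLS3A_noDox replicate 2 (0.0496) or NLS3A_withDox replicate 1 (0.026). ATF4 targets were called without WT_noDox replicate 2 (0.0091), WT_withDox replicate 3 (0.013) or NLS3A_noDox replicate 3 (0.012), and interferon-stimulated genes without NLS3A_noDox replicate 3 (0.0045) or NLS3A_withDox replicate 3 (0.047). NRF2 targets (0.018) and histone genes (0.012) were called without WT_noDox replicate 2, and lung epithelium markers without NLS3A_noDox replicate 3 (0.048). The list test pointed down for secreted factors (median 0.018) and up for fibroblast markers (median -0.037).

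Before induction the lines differed in few genes. The highest in NLS3A were MUC5B (727897), a secreted airway mucin (1.46 ± 0.24, from 4.39 ± 1.23 to 12.5 ± 4.38 CPM), and SPDEF (25803), a transcription factor of mucous cells (1.27 ± 0.19, from 4.17 ± 0.535 to 10.02 ± 2.57 CPM). Glutathione peroxidase GPX2 (2877) was higher by 0.86 ± 0.11 and the fibrinogen chain FGB by 0.79 ± 0.10, and both passed without any 1 library. PRC1 (-0.02 ± 0.08), CDKN1A (0.05 ± 0.08) and MDM2 (-0.05 ± 0.08) did not pass before induction. In total 18 genes were higher and 0 lower in NLS3A, with 895 at an unadjusted p under 0.05, and DESeq2 called 37 and 14 and limma-voom 8 and 0. When the 6 non-induced libraries were fitted alone 0 genes passed, with 582 at an unadjusted p under 0.05.

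Most of these calls moved with single libraries. MUC5B was not past the test without WT_noDox replicate 3 (adjusted p = 0.18), WT_withDox replicate 1 (0.053), NLS3A_noDox replicate 1 (0.14) or 2 (0.25) or NLS3A_withDox replicate 1 (0.052). SPDEF was not without NLS3A_noDox replicate 1 (0.086) or 2 (0.12), nor was the ribonuclease RNASE4 (0.94 ± 0.14) without these (0.086 and 0.12) or WT_noDox replicate 3 (0.094). Ceruloplasmin, CP (1.03 ± 0.18), SELENBP1 (0.84 ± 0.15) and the fibrinogen-like FGL1 (0.83 ± 0.15) were not without WT_noDox replicate 3, WT_withDox replicate 2, NLS3A_noDox replicate 1 or 2 or any NLS3A_withDox library (0.0559 to 0.416). CP and SELENBP1 were not without WT_withDox replicate 1 (0.0533 and 0.0584) or 3 (0.0713 and 0.0760) either. The number of higher genes was 39 without WT_noDox replicate 1 or NLS3A_noDox replicate 3, 5 without WT_noDox replicate 3 and 4 without NLS3A_noDox replicate 1 or 2. It was 9, 9 and 10 without WT_withDox replicates 1, 2 and 3, and 8, 8 and 9 without NLS3A_withDox replicates 1, 2 and 3. The number of lower genes was 56 without WT_noDox replicate 1, 5 without WT_noDox replicate 2 and 2 without NLS3A_noDox replicate 3.

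With the preset correlation 6 lists differed between the non-induced lines, and with an estimated one 0 did (lowest adjusted p = 0.24). In NLS3A the medians were -0.05 for G2/M genes (adjusted p = 0.24 with an estimated correlation), -0.06 for G1/S genes (0.31), -0.13 for ATF4 targets (0.24) and -0.12 for YAP/TEAD targets (0.34), and 0.07 for NRF2 targets (0.31) and 0.06 for lysosome genes (0.24). Of all list members only BCL3 (NF-kB early genes), GPX2 (NRF2 targets) and MUC5B (lung epithelium markers) passed. Adjusted over the list alone, 5 G2/M genes and 1 histone and 1 NF-kB gene were lower. In the same way 4 NRF2 targets, 2 histone genes, 2 NF-kB genes and 1 gene each of the secretion, YAP/TEAD and lung epithelium lists were higher, and 0 of the other lists. For chaperone genes the test pointed down with a median of 0.0058.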

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

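The test of the PRC1 dose, that of drift shared by a list's members and the fit with a ribosomal protein covariate were chosen after the results were seen. In 10 of 22 gene lists the response to induction differed between the lines by camera with the preset correlation. The median difference of log2 changes, NLS3A minus WT, was -0.11 for p53-activated genes, 0.032 for G2/M and mitosis genes, 0.071 for G1/S and DNA replication genes and 0.10 for tubulin genes. It was 0.67 for mitochondrially encoded mRNAs, 0.21 for nuclear OXPHOS genes, 0.28 for ribosomal protein genes, 0.065 for chaperone and unfolded protein genes, -0.10 for YAP/TEAD targets and -0.12 for epithelial-mesenchymal and matrix genes. With an estimated correlation, 9 of the 10 lost the call (adjusted p from 0.37 to 0.42), all but the p53 list (0.0078). For lists called in both lines in the same direction with the preset correlation, mean log2 changes were compared as NLS3A over WT. The ratio was 0.81 for p53, 0.88 for G2/M, 0.83 for G1/S, 0.78 for interferon, 0.72 for ATF4 and 0.98 for lysosome genes. These ratios do not set the p53 list apart. Its estimated correlation was -0.0046, against 0.041 for G2/M and 0.077 for G1/S genes, which makes its test less strict.

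The p53 list rose less in the NLS3A line. Its mean log2 CPM was 5.90 to 5.91 in induced WT and 5.79 to 5.81 in induced NLS3A libraries, and 5.24 to 5.29 in the 6 non-induced libraries. A single library may decide the call: without WT_noDox replicate 1 the adjusted p with an estimated correlation was 0.155, and without each of the 11 others it was at most 0.033. The median difference stayed between -0.15 and -0.10 in these 12 fits and was largest in size, at -0.15, without WT_noDox replicate 1. The smaller rise thus does not rest on that library, though the call with an estimated correlation does. A lower dose of PRC1 in the NLS3A line could also contribute and cannot be told apart from an effect of the mutation, since the difference in PRC1 log2 change was -0.118 with a 95% interval of -0.35 to 0.12.

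The ribosomal protein, OXPHOS and mitochondrial lists also moved apart in the 2 lines. Their members rise and fall together from library to library, with estimated correlations of 0.88, 0.74 and 0.91 in the difference between the lines. The lowest adjusted p of the 3 lists with that correlation was 0.375, which is consistent with drift between libraries that the members share. With the ribosomal protein level as a covariate, the median difference of nuclear OXPHOS genes was -0.020 and that of mitochondrially encoded mRNAs 0.59, so drift along the ribosomal protein level alone leaves the mitochondrial difference in place. Over all alternatives the mitochondrial difference ranged from 0.17 to 0.98, so its size depends on the libraries and settings used. The mean log2 CPM of the ribosomal protein list was 8.95 and 9.58 at its extremes within the non-induced WT libraries, and the share of mitochondrially encoded mRNAs was 1.06% in WT_withDox replicate 3 against 2.40% and 3.19% in its replicates. Whether the NLS3A protein itself moves these transcripts was not tested by a design that separates it from this drift.

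The number of genes with a different response was 0, which every regrouping of the libraries within lines reaches by construction (100 of 100), so that count decides nothing about chance. Of the 100, 97 gave 0 genes, and the highest other, with 113, kept the real groups of the WT line and mixed those of the NLS3A line.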

How the results depend on the processing

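Both forms of the covariate, the fit without a pair of doubted libraries and the fit without mitochondrial genes were chosen after seeing the data. The p53, G2/M, G1/S and interferon lists kept their direction and call in each line under all 27 alternatives, with p53 medians of 0.55 to 0.61 (WT) and 0.44 to 0.51 (NLS3A). The p53 list kept its lower response in NLS3A under all 25 by camera with the preset correlation (median difference -0.16 to -0.10). With an estimated correlation it was lost without WT_noDox replicate 1 (adjusted p = 0.15), with library totals alone (0.088) and with a replicate block within each line (0.11). Of 73 named genes past the test in the WT line, 53 kept it in every fit, of 60 in the NLS3A line 41 did, and of 10 between non-induced lines 0 did. The cause was not tested for any change below, except that a minimum change makes the count smaller by construction. Leaving out libraries raised some counts and lowered others.

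Counts of genes are given as higher and lower, and larger and smaller changes refer to the sign of NLS3A minus WT. Each line fitted alone gave 329 and 280 in WT, 857 and 929 in NLS3A, so the order of the lines turned, and 0 higher between non-induced lines. The ribosomal protein covariate centred within groups, which does not adjust for differences in that level between groups, gave 2062 and 2271 in WT, 981 and 1131 in NLS3A, 179 larger and 68 smaller changes in the difference between the lines, and 139 and 110 between non-induced lines. Not centred, so that group differences are adjusted too, it gave 1400 and 1513, 1055 and 1336, 0 larger and 4 smaller, and 151 and 120. With it the median of OXPHOS genes turned to -0.079 in NLS3A and -0.020 in the difference, and that of ribosomal protein genes to -0.023 in NLS3A, which for ribosomal protein genes follows from the adjustment. Without WT_noDox replicate 2 and WT_withDox replicate 3, NLS3A had 558 and 619, WT 609 and 613, the difference between the lines 0 and 0, and non-induced lines 17 and 2. An absolute log2 change of at least 1 left 121 and 9 in WT, 59 and 7 in NLS3A and 3 higher between non-induced lines. Between non-induced lines, no filter gave 38 and 8, DESeq2 37 and 14 and limma-voom 8 higher.

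The replicate block within each line gave 1299 and 1440 in WT, 528 and 589 in NLS3A, and 1 larger change in the difference; the block over both lines gave 1 lower gene between non-induced lines. Deviations of same-numbered libraries had correlations of 0.40, 0.19 and 0.05 in WT and -0.03, -0.03 and -0.10 in NLS3A. Differently numbered libraries had -0.33 to 0.13 in WT and -0.07 to 0.10 in NLS3A. The numbers thus show no pairing in NLS3A, while pairing in WT stays open.

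Without 1 library at a time, WT gave 422 to 1843 higher and 427 to 2189 lower, NLS3A 170 to 560 and 172 to 648, the difference 0 to 186 larger and 0 to 48 smaller, and non-induced lines 4 to 39 higher and 0 to 56 lower. The highest of each came without WT_noDox replicate 1, tied with NLS3A_noDox replicate 3 for genes higher between non-induced lines. In WT the median of mitochondrially encoded mRNAs ranged from -0.42 without WT_withDox replicate 1 to a called 0.35 without WT_withDox replicate 3, and was 0.53 without both doubted libraries. That of ribosomal protein genes ranged from -0.36 without WT_noDox replicate 1 to -0.020 without WT_noDox replicate 2, where the direction of the list test turned. Genes near 1 CPM are limited by depth.

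For the number of genes changed, 10 splits are too few for a share under 0.05. In the WT line 1 of 10 gave as many as the real 1685, with 267 as the highest other; in the NLS3A line 1 of 10, with 726 against 0; between non-induced lines 1 of 10, with 18 against 6.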

Other observations

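The tests in this part were chosen after the results were seen, except the fit without WT_noDox replicate 1. Genes outside the fixed lists that changed in both lines included TRIML2 (1.45 ± 0.10 in WT, 1.66 ± 0.11 in NLS3A), at 66.4 ± 7.21 and 69.4 ± 3.68 CPM after induction, and the imprinted RNA H19 (-1.02 ± 0.17 and -1.26 ± 0.16). Among the smallest p-values of the difference between the lines were those of CD38 (-0.92 ± 0.20), the mucin MUC3A (-0.85 ± 0.19) and TPPP3 (-1.18 ± 0.29). All of these had a lower log2 change in NLS3A than in WT, and none passed adjustment (adjusted p = 0.92). MTRNR2L8, uncertain as a single gene, ranked next with the opposite sign, at 1.33 ± 0.33 (adjusted p = 0.92). It fell in WT (-0.96 ± 0.23, adjusted p = 0.015) and did not pass in NLS3A (0.36 ± 0.24, adjusted p = 0.47). DDIT3, a stress-induced transcription factor, had a difference of 0.67 ± 0.18 (adjusted p = 0.92). With a ribosomal protein covariate not centred within groups, TPPP3 was at -1.46 and past the test (adjusted p = 0.0018), while CD38 (0.21), MUC3A (0.49) and DDIT3 (0.81) were not. Without WT_noDox replicate 1 these genes passed (0.028 for CD38 and MUC3A, 0.049 for TPPP3, 0.044 for DDIT3). Over the alternatives the adjusted p ranged from 0.0013 to 1.00 for TPPP3, from 0.0051 for CD38, 0.0084 for MUC3A and 0.026 for DDIT3 to the same upper value.

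Without WT_noDox replicate 1, 234 genes had a different response in the 2 lines, and with the ribosomal protein covariate centred within groups 247 did. Of these, 162 were shared, all with the same sign, where independent lists would share 4.23, though the fits share 11 libraries and are not independent. Among the 162 were 26 ribosomal protein and 10 nuclear OXPHOS genes. Both settings act on ribosomal protein genes directly, so their number here is no separate evidence of a different response. The centred covariate is their own mean level, which takes out their spread within groups and leaves their group differences. WT_noDox replicate 1 had the lowest mean log2 CPM of ribosomal protein genes of all libraries (8.95). With the covariate not centred, which also adjusts for differences between groups, 4 genes had a different response.

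The rise of p53-activated genes and the fall of cell-cycle genes in both lines were weighed against 3 explanations. Drift of ribosomal protein transcripts is argued against as the cause of the p53 rise in the WT line. With group differences adjusted for their level, 45 of 53 p53-list members were higher there. That level differed little between the WT groups (9.26 ± 0.31 non-induced, 9.12 ± 0.12 induced), so the adjustment had little to remove. Over all alternatives, this covariate included, at least 29 p53-list members were higher in NLS3A. At least 56 G2/M and 43 G1/S genes were lower in WT, and 42 and 27 in NLS3A. Doxycycline inhibits mitochondrial translation, and a stress response by that route would raise ATF4 targets, whose median was -0.207 in WT and -0.17 in NLS3A, with upper quartiles of -0.09 and -0.08. Doxycycline acting by another route cannot be told apart from PRC1, because 0 doxycycline-treated libraries without a PRC1 construct were analysed here. Induced PRC1 thus stays a hypothesis as the source of these changes.

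A hypothesis for the 18 genes higher in the non-induced NLS3A line is a lasting difference between the lines. All 18 were also higher in induced NLS3A than in induced WT libraries, which are other libraries, at an unadjusted p under 0.05. Of all genes tested, 15.5% reached that level in either direction. Both contrasts share 1 estimate of each gene's spread, on which the 18 were also chosen, so the 15.5% is not a strict reference. All 18 kept their sign, with median log2 differences of 0.75 before and 0.46 after induction. This is consistent with such a difference. Between the induced lines 1 gene higher and 1 lower passed adjustment, FGB being the higher one (adjusted p = 0.0059), and the 18 genes are not independent of each other.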
